A study of Medicago truncatula with 6 samples.

How the data were processed

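RNA was taken from nodules of wild type and mtbzr1-1 plants, 3 libraries each, and sequenced on a BGISEQ instrument, per the labels' protocols. Adapters, low-quality reads and reads rich in unknown bases were removed with Trimmomatic, per the submitters' design text. Bowtie is named without a version, per the submitters' processing notes. The expression counter, the genome build and the annotation are not given in the sources used here. The authors deposited expression as FPKM per library, rounded to 2 decimals, per the file headers. The log2 fold changes of the authors are mutant over wild type, and the q-values come from DEGseq, per the file headers. In the deposited gene table every gene had an absolute log2 fold change above 1 and a q-value below 0.001, so it holds 1319 selected genes, 618 higher and 701 lower, and not all genes. The authors also deposited enrichment p-values and q-values for functional terms, and principal components and correlations over 35401 genes.

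Such a selection favours genes with large folds and many reads, and a test run on its genes finds most of them changed. FPKM divides by transcript length and depth, and reads shared between near-identical genes can be split between them. Identical values in all 6 libraries were shared by 14 genes, which formed 7 sets. Of the genes with 1 transcript, 97.6% had a length that is a multiple of 3, so these are coding lengths.

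Libraries were grouped by the genotype in the labels. Because the values are FPKM and the genes are selected, the count test planned for counts and the competitive gene set test planned for a complete table were not used. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trended prior, for the 936 genes with a mean of at least 1 FPKM. The Benjamini-Hochberg threshold was an adjusted p of 0.05. Fold changes on the log2(FPKM + 1) scale understate the change of low genes, so the folds printed are ratios of mean FPKM. No exact test of 3 against 3 libraries on a single gene can go below p = 0.1. The direction of each gene list was tested with a 2-sided Fisher's exact test of higher against lower called members and the rest of the called genes, adjusted over 15 lists with called members (scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and Python 3.11.15). Genes are not independent replicates, and co-regulated members make such a p too small.

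Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names the 5 largest rises and 5 largest falls among called genes with non-overlapping genotypes and a mean of at least 10 FPKM, ranked by fold change on the log2(FPKM + 1) scale, plus up to 2 called members of each list with the smallest adjusted p, plus any BZR1/BES1 member. Lists were matched by words in the gene descriptions, which admits spelling matches. Sets of functional pathways, transcription factor families and description families were examined after the values were seen. Those comprised the 7 enriched pathways, 6 transcription factor families with at least 5 genes and 10 description families, of which 9 were tested, each kind with its own correction.

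Depth was estimated from the steps between low FPKM values, as the number of reads that made the values nearest to whole multiples. Within 0.15 reads, 74.5% to 78.6% of the low values lay near a whole number, and the estimates were 15050000 to 15300000 reads. At a depth fixed in advance 30.0% would lie so near by chance. The depth and a length offset were fitted to these same values, so the share by chance after fitting can be higher and was not estimated. Reads per gene were not recovered, so no count test was run. The median coefficient of variation between libraries was 13.6% in wild type and 14.4% in mtbzr1-1 for genes with an estimated 20 to 100 reads, and 2.6% and 2.1% for those with 1000 or more. Libraries of a genotype differed by more than counting noise, with a mean chi-square of 1.67 to 2.16 per gene, but the median-based value was 1.13 to 1.38, so the typical gene lay close to counting noise and the excess came from part of the genes. On the mean value, no pair was treated as repeat deposits of the same library.

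The limma step was tested on simulated data for mtbzr1-1 against wild type with 940 genes. It called 64.2% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 100% of those changed 4-fold, and 12 of 740 unchanged genes. Simulated reads varied by counting noise plus a small fixed spread, so part of the real genes varied more. Most simulated genes were unchanged, whereas the real genes were selected as changed. These rates therefore describe the simulated setting and may be too favourable for the real libraries. On 1000 random lists of 51 called genes, Fisher's exact test gave p under 0.05 in 4.1%.

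Alternatives were a replicate block, a pseudocount of 0.1, no low-value filter, median centring, a fold limit, an adjusted p of 0.01, leaving out each library and the authors' calls. Added after seeing the data were an adjustment over 35401 genes, counting identical genes once and the symbiotic signalling and brassinosteroid lists without spelling matches. Coordinates are printed as in the deposited table. A gene reference of another assembly shared no identifiers with the table and was not used here.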

Results

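The data are RNA-seq profiles of root nodules of Medicago truncatula, a legume that forms nitrogen-fixing nodules with the soil bacterium Sinorhizobium meliloti. Nodules were collected 28 days after inoculation from wild type plants and from the mtbzr1-1 mutant, with 3 libraries per genotype. MtBZR1 belongs to the BZR1/BES1 family of transcription factors, which act in brassinosteroid signalling, and the comparison addresses which nodule transcripts differ when the gene is mutated. The values are FPKM of 1319 genes that the authors had already selected as differing between the genotypes. The steps between low FPKM values gave estimated depths of 15050000 to 15300000 reads per library, so depth was nearly equal between the genotypes. The labels do not say whether the libraries of a genotype came from separate plants, and the p-values therefore measure only the spread between these libraries, which may be technical.

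No gene described as BZR1, BES1 or brassinazole-resistant was among the genes used, so the targeted gene is not analysed here and the genotype labels were not checked by it. The list of brassinosteroid pathway genes had 1 member in the table, which matched through the word steroid in a 5-beta-reductase description and lay below the expression minimum.

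Among the selected genes, nodules of mtbzr1-1 had lower transcript levels of 49 secreted nodule cysteine-rich peptides and of a disease-resistance response gene. Levels of 2 legume lectins, an aspartyl protease and a chitinase were higher. Of the 936 genes with a mean of at least 1 FPKM, 923 passed an adjusted p of 0.05 in limma, 404 higher and 519 lower in the mutant. The median fold was 2.57 among the genes that rose and 2.67 among those that fell. For 909 of the 923 genes the 3 mutant values did not overlap the 3 wild type values, and over the whole table this held for 1240 genes, or 94.0%. Chance gives 10% for genes not chosen by their values, but these genes were selected for differing between the same 6 libraries, which largely fixes that share. Because the table holds selected genes only, the adjusted p covers those genes and not the transcriptome, and these counts say nothing about genes outside it. When an absolute log2 fold change of at least 1 on the log2(FPKM + 1) scale was also required, 611 genes passed.

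**Figure D1:**
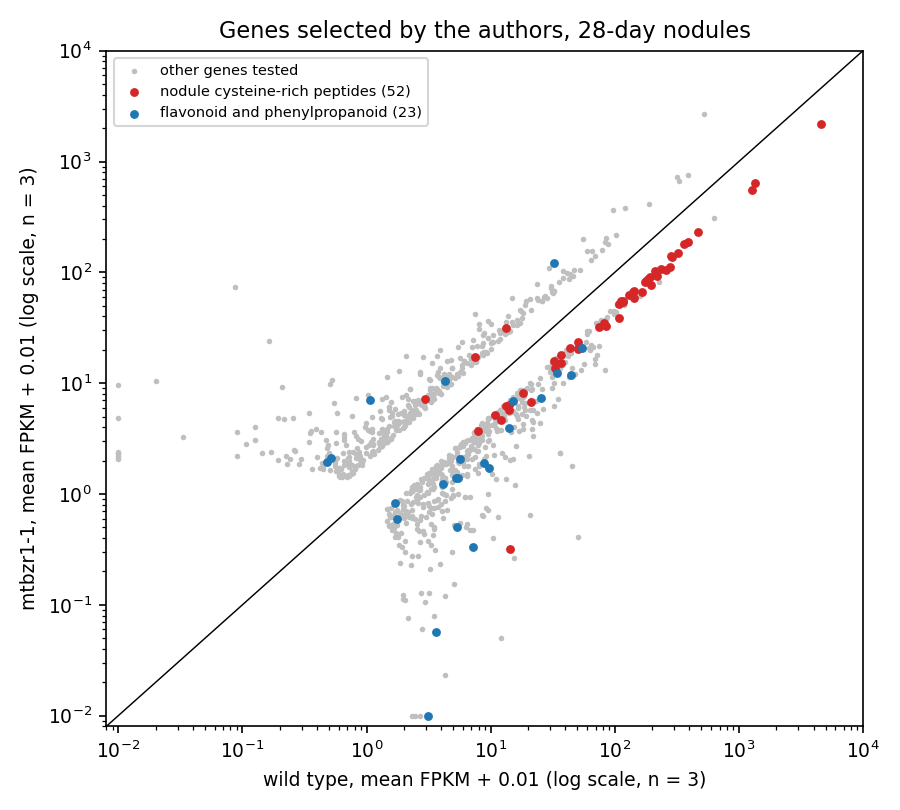
Mean FPKM of each tested gene in wild type (x axis) and mtbzr1-1 (y axis), 3 libraries each, with 0.01 FPKM added and both axes on a log scale. The line marks equal levels, the empty band around it comes from the authors' selection of changed genes, and 49 of the 52 nodule cysteine-rich peptide genes (red) fell in the mutant.

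Among genes with a mean of at least 10 FPKM, ranked by fold change on the log2(FPKM + 1) scale, the largest rises were those of 2 legume lectin genes, which encode carbohydrate-binding proteins. Medtr1g090957 (chromosome 1, 41065567 to 41066415) reached 73.5 ± 2.32 FPKM (SD, n = 3) in mtbzr1-1 and was listed at 0, 0.23 and 0 FPKM in the wild type libraries. Medtr3g027280 (chromosome 3, 8495722 to 8496567) rose from 0.153 ± 0.0404 to 24.3 ± 1.78 FPKM (SD, n = 3). The aspartyl protease gene Medtr3g006820 (chromosome 3, 885806 to 887691) was already abundant in wild type, at 519.9 ± 5.08 FPKM, and rose 5.14-fold to 2672 ± 49.9 FPKM. Medtr1678s0010, described as a pollen Ole e I-like protein, rose 5.61-fold, and the putative transmembrane protein gene Medtr6g084790 rose 5.16-fold. The limma adjusted p of these 5 genes lay between 8.25e-10 and 7.61e-06.

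By the same ranking and level, the largest fall was that of Medtr2g035150, a disease-resistance response gene (chromosome 2, 13514737 to 13515378), from 50.5 ± 5.44 to 0.40 ± 0.229 FPKM (SD, n = 3). The expansin-B1-like gene Medtr4g099400 (chromosome 4, 41244357 to 41245315), from a family of proteins that loosen cell walls, fell 25.4-fold, from 45.2 ± 2.59 to 1.78 ± 0.0872 FPKM. Medtr2g022490, an extracellular dermal glycoprotein gene, fell 32.7-fold. The pathogenesis-related Bet v I identifiers Medtr4g120970 and Medtr6g033450 fell 15.3-fold, from 35.9 ± 3.00 to 2.34 ± 0.403 FPKM. These 2 identifiers carry the same coordinates (chromosome 6, 10797135 to 10797689) and identical values, so by the deposited coordinates the 5 largest falls of this ranking stand for 4 loci. Whether the 2 identifiers are 1 gene or identical copies cannot be told from these values. The limma adjusted p of these 5 falls lay between 3.46e-08 and 2.41e-07. Genes with lower means, which the ranking leaves out, include some with larger changes, such as Medtr6g034195, a pyruvate kinase gene at a mean of 12.2 FPKM in wild type and 0.04 FPKM in mtbzr1-1, and the receptor gene Medtr7g092910, listed at 0.03, 0 and 0 FPKM in wild type and at 10.4 ± 0.19 FPKM (SD, n = 3) in the mutant, both chosen after their values were seen. Coordinates are those of the deposited table, whose genome build is not given in the sources used here.

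**Figure D2:**
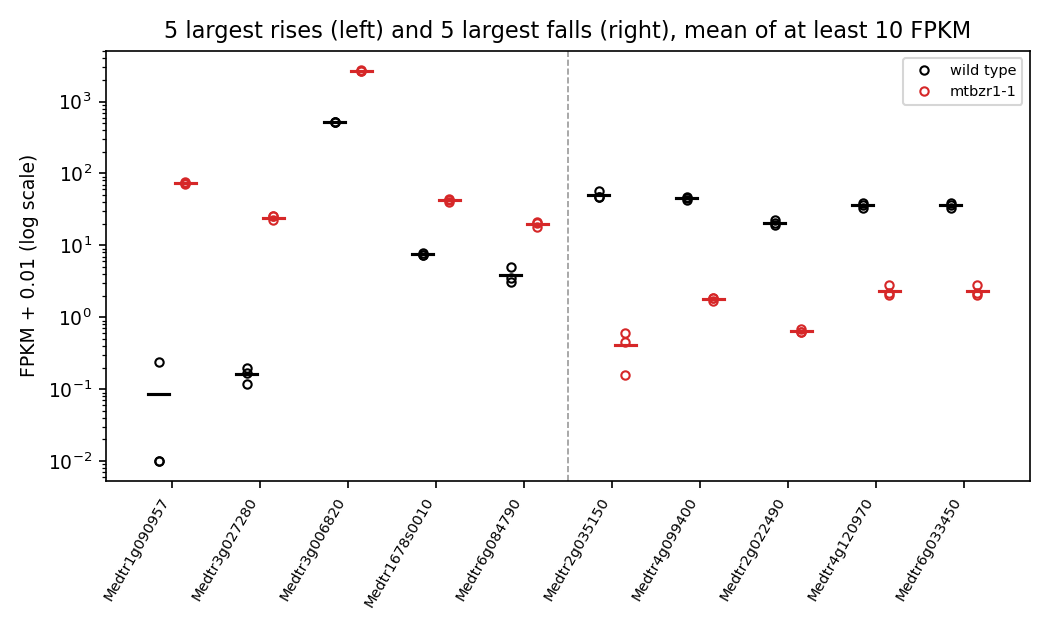
FPKM of the 5 genes with the largest rises (left of the dashed line) and the 5 with the largest falls (right) on the log2(FPKM + 1) scale among genes with a mean of at least 10 FPKM, plotted with 0.01 FPKM added and a log axis. Circles are the 3 libraries of wild type (black) and mtbzr1-1 (red) and bars are their means. Genes were chosen among those whose genotypes do not overlap, and the last 2 identifiers carry the same coordinates and identical values.

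Nodule cysteine-rich peptides are secreted towards the bacteria inside nodule cells, and nearly all of their genes in the table were lower in mtbzr1-1. Of the 52 members in the table, 49 were lower, 2 were higher and 1 did not pass the test. The most strongly supported were Medtr6g445080 (chromosome 6, 15610605 to 15611035), which fell 2.09-fold from 4575 ± 78.1 to 2188 ± 16.8 FPKM (SD, n = 3), and Medtr7g045520 (chromosome 7, 16031889 to 16032191), which fell 2.11-fold from 1358 ± 7.19 to 643 ± 9.68 FPKM. The median fold of the 49 members that fell was 2.15. The members together summed to 13457 FPKM in wild type and 6288 FPKM in the mutant, of which Medtr6g445080 alone gave 4575 and 2188 FPKM. Each member was selected for a change above 2-fold, so the size of the drop in the sum follows largely from the selection. Lower members made up 96.1% of the called members against 53.9% of the other called genes (2-sided Fisher's exact test, p = 7.01e-11, adjusted p = 1.05e-09 over 15 lists). Adjusted over the list alone, 51 members passed. Most of these folds lie close to the selection limit of the table, so members that changed by less than 2-fold are not analysed here, and the share describes selected members rather than the whole family. The peptides form a large gene family, and values of near-identical copies are uncertain where the authors' counting split shared reads.

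Both nodule-specific glycine-rich peptide genes of the table also fell. Medtr2g039235 went from 119 ± 12.1 to 50.8 ± 1.73 FPKM and Medtr2g439230 from 8.82 ± 2.16 to 2.05 ± 1.15 FPKM (SD, n = 3). No leghemoglobin, early nodulin or cell cycle gene of the lists was among the genes used. In the symbiotic signalling list, 4 of the 5 tested members rose and 1 fell (Fisher's exact adjusted p = 0.717). The remorin gene Medtr7g091990, from a family of plasma membrane proteins, rose 2.08-fold. Medtr3g061630, which rose 2.03-fold, is a chaperonin-like RbcX gene that entered the list only by spelling. The sugar transporter gene Medtr3g090940, the only member of the nitrogen and carbon assimilation list in the table, rose 2.47-fold, from 1.67 ± 0.305 to 4.11 ± 0.299 FPKM.

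Flavonoid and phenylpropanoid genes moved in both directions, with more members lower. Of the 33 members in the table, 23 were tested, and 18 fell while 5 rose. The leucoanthocyanidin dioxygenase-like gene Medtr3g070860 fell 3.76-fold, from 44.1 ± 1.31 to 11.7 ± 0.301 FPKM, and the flavonoid glucosyltransferase gene Medtr3g084520 rose 3.73-fold, from 32.5 ± 2.51 to 121 ± 2.71 FPKM (SD, n = 3). The 78.3% of lower members against 55.7% of the other called genes had a raw Fisher's exact p of 0.0337 and did not pass the correction over 15 lists (adjusted p = 0.253). Adjusted over the list alone, 23 members passed.

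**Figure D3:**
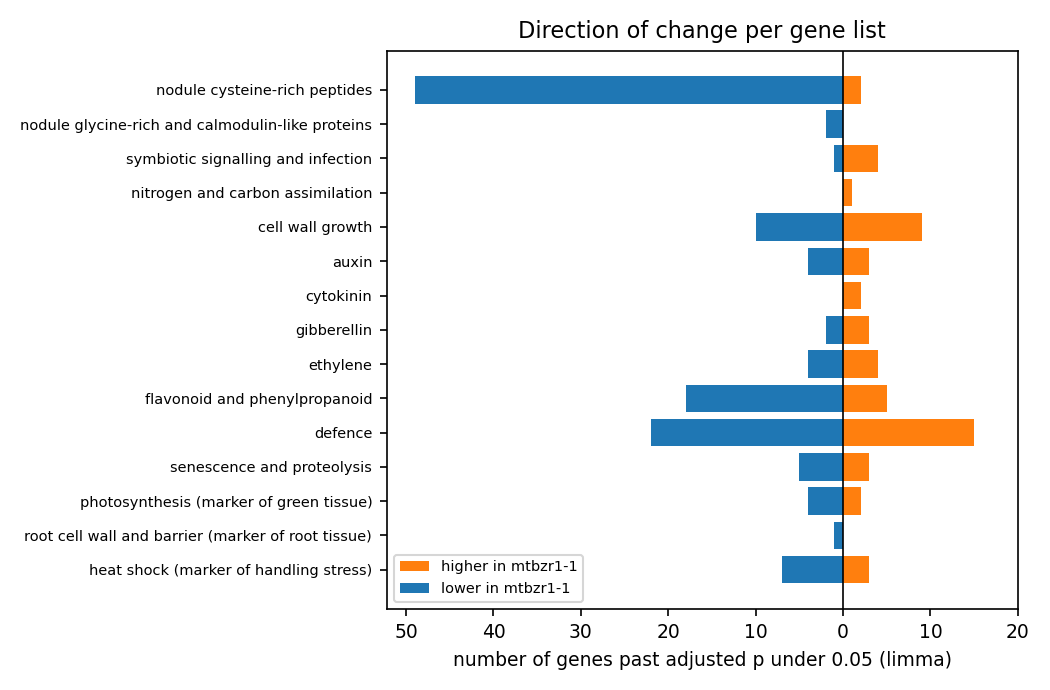
Number of genes per list that passed an adjusted p of 0.05 in limma, higher in mtbzr1-1 to the right (orange) and lower to the left (blue). The nodule cysteine-rich peptides, with 2 higher and 49 lower, are the list whose direction passed the correction over 15 lists.

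Cell wall genes were split, with 9 higher and 10 lower of 19 tested (Fisher's exact adjusted p = 1). The lower members include polygalacturonase inhibitor genes, such as Medtr8g466220, which the word polygalacturonase admitted. The tested xyloglucan endotransglucosylase genes all fell, while the tested pectinesterase genes rose except Medtr7g108875. These subsets were picked after the values were seen and not tested. Expansin genes went in opposite directions: besides the fall of Medtr4g099400, the expansin-like B1 gene Medtr0118s0070, named after its values were seen, rose 3.88-fold, from 7.98 ± 0.90 to 31.0 ± 1.17 FPKM (SD, n = 3). The xyloglucan endotransglucosylase/hydrolase gene Medtr4g128580 fell 6.29-fold, from 83.2 ± 1.52 to 13.2 ± 1.19 FPKM. Hormone-related lists did not lean to either side past the correction. Among auxin-related genes 3 rose and 4 fell, among them the auxin-induced 5NG4-like gene Medtr2g007990, which rose 2.24-fold, and the auxin-repressed gene Medtr2g014240, which fell 2.57-fold. Both tested cytokinin genes rose, the cytokinin oxidase gene Medtr3g112350 by 2.27-fold and the isopentenyltransferase gene Medtr2g022140 by 2.46-fold; the former enzyme degrades cytokinin and the latter makes it. In the gibberellin list 3 rose and 2 fell. The gibberellin 20-oxidase gene Medtr1g102070 fell 2.96-fold and the gibberellin-regulated gene Medtr4g106860 fell 2.71-fold. In the ethylene list 4 rose and 4 fell, with the ethylene response factor gene Medtr1g048610 rising 2.12-fold to 219 ± 10.4 FPKM and Medtr8g006840 falling 15.5-fold to 0.46 ± 0.11 FPKM. The Fisher's exact adjusted p was 0.717 for cytokinin and 1 for auxin, gibberellin and ethylene. With 2 tested genes, both higher, the cytokinin list was too small to pass.

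Defence genes also moved both ways, with 15 higher and 22 lower of 37 tested (Fisher's exact adjusted p = 1). The 22 count both Bet v I identifiers that share coordinates and values. The disease-resistance response gene Medtr2g035150, the largest fall named above, is not in this list, because the hyphen in its description escaped the match. The chitinase gene Medtr2g040650 rose 3.14-fold, from 121 ± 4.25 to 379.7 ± 3.63 FPKM (SD, n = 3), while the Bet v I gene Medtr6g033450 fell. In the senescence and proteolysis list 3 rose and 5 fell (adjusted p = 1). Papain family protease genes went in opposite directions, with Medtr4g080700 falling 4.87-fold, from 34.8 ± 1.08 to 7.14 ± 0.246 FPKM, and Medtr4g065077 rising 3.65-fold, from 55.1 ± 4.90 to 201 ± 4.24 FPKM.

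Markers of other tissues and of handling stress showed no direction past the correction (Fisher's exact adjusted p = 1 for each list). The root list had 1 tested gene and the photosynthesis list 6. Even if all of these had fallen, neither list could have passed, so the test does not decide whether such tissue differed. Of the photosynthesis genes 2 rose and 4 fell, and leaving out any of the 6 libraries reduced the 2 to 1 or 0. Part of this loss comes from the expression minimum. The rising gene Medtr5g018670, at 1.69 ± 0.176 FPKM in mtbzr1-1 and 0.437 ± 0.140 FPKM in wild type (SD, n = 3), lay just above the minimum mean of 1 FPKM. Leaving out a mutant library took that gene below the minimum, so it was no longer tested. Medtr7g079900, a photosystem I subunit gene, fell from 6.54 ± 0.465 to 2.28 ± 0.221 FPKM, and the light-harvesting gene Medtr6g011890 fell from 2.63 ± 0.419 to 0.457 ± 0.176 FPKM. The casparian strip membrane protein gene Medtr4g081880, a marker of the root endodermis, fell 2.80-fold. Of the heat shock genes 3 rose and 7 fell. The 7 include Medtr5g082150, a nematode resistance HSPRO2-like gene that entered the list only by spelling. The heat shock cognate gene Medtr4g063710 fell 2.51-fold and the small heat shock gene Medtr0004s0510 fell 2.06-fold.

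In the authors' deposited table of enriched terms, nodule morphogenesis held 56 of the selected genes against 624 annotated genes, with a q-value of 2.29e-10. Of these 56 genes, 53 were lower and 3 higher by the authors' deposited table, and 52 were the nodule cysteine-rich peptides described above, so the term and the list are not independent. Isoflavonoid biosynthesis, with 19 selected genes and a q-value of 5.91e-07, was the top pathway in the authors' deposited table, and monoterpenoid biosynthesis followed with 11 selected genes and a q-value of 9.52e-07. The deposited p-values of 108 pathways and 1591 terms equalled a hypergeometric test within 0.01 on the log10 scale, and 7 pathways and 49 terms had a q-value under 0.05 in the authors' deposited table.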

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

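The adjustment over 35401 genes, the counting of identical genes once and the lists without spelling matches were chosen after seeing the data. The 923 differentially expressed genes became 923 with a replicate block, 917 with a pseudocount of 0.1, 1266 without the low-value filter, 918 with median centring, 895 at an adjusted p of 0.01, 919 with identical genes counted once and 783 when adjusted over 35401 genes. Requiring an absolute log2 fold change of at least 1 left 611 genes, 252 of them higher, because folds on the log2(FPKM + 1) scale are smaller than FPKM ratios at low levels. The authors' calls count 1319 genes, 618 of them higher, and take in 383 genes under the expression minimum and 13 tested genes that limma did not call; the test differs as well, and the cause was not tested further. Leaving out single libraries gave 897 to 915 genes. Median centring shifted fold changes by 0.19 (log2) and moved the share of higher genes from 43.8% to 44.6%.

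Replicate numbers showed no sign of pairing the libraries, although a weak pairing could be missed because the typical gene lay close to counting noise. Deviations of same-numbered libraries correlated at -0.073, 0.027 and -0.096 across genes. The block model shared 918 calls with the model without it, which the selection of changed genes makes likely with or without pairing.

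The lower share of nodule cysteine-rich peptides stayed at 94.1% to 96.1%, with adjusted p from 1.25e-10 to 8.99e-08, under every alternative run. The flavonoid and phenylpropanoid share ranged from 68.8% to 81.8%, with adjusted p from 0.204 to 0.56, so it passed under none of those run. For 36 named genes, 534 of 539 values under alternatives kept direction and side of the threshold, 0 reversed, and 5 lost the call, all under the fold limit. All genes used here were selected for differing between the same 6 libraries, and the named genes were also picked as called. Stable directions and calls, for the named genes and the peptide share alike, are therefore largely fixed by the selection. Counts of higher or lower members of single lists moved by over 1.5 times in 36 cases, most of them counts of few genes. Without spelling matches the symbiotic signalling list had 3 higher and 0 lower members. Depth limits genes of few reads most. Alternatives that need counts (DESeq2, voom and size factors) were not run.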

Other observations

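Families and pathways in this part, the neighbour tests without equal descriptions and without relatives, the levels that define genes near 0 and the test on leguminosin genes were chosen after the values were seen. The DOF transcription factor genes of the table, all selected for differing between the genotypes, were higher in mtbzr1-1. All 6 in the table were higher by the authors' deposited table and the 5 tested rose, among them Medtr5g041400 from 0.76 ± 0.14 to 5.03 ± 0.656 FPKM and Medtr7g010950 from 3.66 ± 0.56 to 11.7 ± 0.20 FPKM (SD, n = 3). The direction of the family did not pass the correction over 6 transcription factor families (Fisher's exact p = 0.0158, adjusted p = 0.0951). All 5 tested genes already lay on the same side, so a family of this size could give no lower p. Genes annotated to the plant circadian rhythm pathway, which include these DOF genes, were 12 higher and 4 lower among 16 tested (adjusted p = 0.0669 over 7 pathways). The pseudo-response regulator gene Medtr8g024260 rose from 3.23 ± 0.117 to 8.97 ± 0.307 FPKM and the salt tolerance-like gene Medtr2g099010 from 38.4 ± 0.806 to 88.3 ± 2.86 FPKM. The sources used here do not give the hour of harvest. All 5 FAR1 family genes of the table fell (Fisher's exact adjusted p = 0.215), such as Medtr0558s0020 from a mean of 35.2 to a mean of 15.8 FPKM. Their raw Fisher's exact p of 0.0716 was the lowest that 5 falling genes could give, so this test could not pass.

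Genes for linalool/nerolidol synthases, which make volatile terpenes, were lower in mtbzr1-1 for 8 of 8 genes by the authors' deposited table. These are not independent cases. Medtr3g063120, Medtr3g063140, Medtr3g063160 and Medtr3g063170 lie together on chromosome 3 (28566348 to 28586467), and Medtr0927s0010 is a partial gene of 279 nt. Reads shared between such relatives and their common regulation were not tested. The 6 tested fell, among them Medtr0927s0010 from 14.5 ± 0.32 to 0.303 ± 0.321 FPKM and Medtr3g063120 from 10.4 ± 1.40 to 0.393 ± 0.162 FPKM (SD, n = 3). This family was picked after its members had been seen, and among 9 description families tested its direction did not pass (Fisher's exact p = 0.0381, adjusted p = 0.343). In the isoflavonoid pathway 12 genes fell and 1 rose (Fisher's exact p = 0.00896, adjusted p = 0.0627 over 7 pathways). The isoflavone 7-O-methyltransferase gene Medtr4g033085 fell from 54.6 ± 0.449 to 20.8 ± 1.66 FPKM and the flavone synthase gene Medtr7g027960 from 7.15 ± 0.54 to 0.32 ± 0.115 FPKM. In both genes the 3 libraries of a genotype lay apart from those of the other, as in 94.0% of the table, a share that the selection largely fixes.

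The 923 genes past the threshold between the genotypes were set against the other splits of the 6 libraries into 3 and 3. Among the 10 splits 1, the real one, gave as many, and the highest other gave 1 gene. The genes of the table were selected for differing under the real split, which fixes this outcome, so the count says nothing about chance. With 10 splits the share also cannot go below 0.1.

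The fall of the nodule cysteine-rich peptide genes was weighed against their short transcripts. If short transcripts lost reads in the mutant libraries, other short genes would fall at a like share. Among 69 other called genes of at most 261 nt, 46 were lower, or 66.7%, against 96.1% of the peptide genes (Fisher's exact p = 6.3e-05), which argues against length as the whole cause, although the longer called genes were at 52.8% and a part due to length stays open. A lower share of bacteria-filled cells is a candidate explanation that would also lower other nodule families. Of 5 called leguminosin and nodule glycine-rich genes 4 were lower, or 80.0% (95% exact interval 28.4% to 99.5%), too few to decide. No gene described as leghemoglobin was among the selected genes, and a fall in such genes short of the selection limit could not be seen here. A direct effect of the genotype on these genes was not tested.

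In 67 genes a mean of at least 1 FPKM in one genotype stood against at most 0.1 FPKM in the other, 31 near 0 in mtbzr1-1 and 36 near 0 in wild type. Reads moving between paralogs predict partners of the same description near 0 in opposite genotypes. Such a partner was found for 6.0% of the genes, under the 17.9% at the 95th percentile of shuffled directions (permutation p = 0.982). This is the outcome set beforehand for no such reads, although the levels that define near 0 were chosen after the values were seen. All 4 genes with a partner carry a generic description that names no family, however. Most of the 67 genes share no specific description with another, so reads moving between paralogs stay open. Among genes with specific descriptions, the word partial ignored, 16 shared a description with another and 2 of these, the patatin-like genes Medtr3g101400 and Medtr0368s0010, were near 0 in opposite genotypes, while the rest of the 16 had no opposite partner; this count was made after the values were seen and not tested. A strain variant or deletion carried by a single genotype predicts neighbours near 0 together. Within 100 kb, 3 pairs were near 0 in the same genotype against a shuffled median of 1 (permutation p = 0.041). This p met the threshold set before the test, but the genes that entered it were defined by the levels chosen later. The pairs were 2 polygalacturonase inhibitor genes (Medtr1g047950 and Medtr1g047960), 2 legume lectin genes (Medtr1g090930 and Medtr1g090957) and the unlike genes Medtr4g033275 and Medtr4g033285. Without pairs of equal description 2 pairs were left (permutation p = 0.11), and without both pairs of relatives 1 pair was left (permutation p = 0.44), so a variant and shared regulation of tandem relatives cannot be told apart.

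The authors' deposited table of correlations gave 0.9990 to 0.9996 between mtbzr1-1 libraries, 0.9991 to 0.9997 between wild type libraries and 0.9926 to 0.9949 between genotypes.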
